A study of Drosophila melanogaster with 4 samples.

How the data were processed

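RNA from whole Drosophila melanogaster larvae at the 3rd instar, grown at 25 °C, was compared on 4 Agilent 2-colour expression arrays. Per the labels, each array carried RNA of the Oregon-R wild type, labelled with Alexa Fluor 555 (green), and RNA of Hdac1 mutant larvae in the same background, labelled with Alexa Fluor 647 (red). The mutant carried 1 copy each of the alleles Hdac1[303] and Hdac1[def8]. The labels name the 4 arrays as biological replicates. Per the labels' protocols, 15 µg of total RNA was reverse transcribed from an oligo-dT primer with an amino-allyl nucleotide and coupled to the dye afterwards. The dyes had the same orientation on all 4 arrays, so any dye effect is part of every mutant over wild type ratio. The file headers place all 4 arrays on 1 slide, scanned in 1 scan, so neither slide nor scan separated the arrays.

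Per the file headers, the scanner images were read with Agilent Feature Extraction 10.5.1.1. The deposited spot intensity values are median pixel intensities of the spot and of its local background in each channel, and background-subtracted and dye-normalized intensities. The deposited log10 ratio of red over green was set to 0 on 2234 to 2718 spots per array. On 50 to 59 of those spots per array at least 1 of the channels was significantly above background, and on the others neither was. The submitters' table of processed values held, spot by spot, the same log10 ratios as the scanner files. Scale, centring and direction of that table were therefore settled, and it added no independent measurement.

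Median spot intensities were background-corrected with normexp at an offset of 50, using limma 3.58.1 in R 4.3.3. The planned mean spot intensities were replaced by medians because the scanner files used here give medians. Log2 ratios of mutant over wild type were normalized within each array by loess, with control spots at weight 0. Loess centres each array, so every change is relative to the bulk of the transcripts on it. Control spots and the 27 to 83 spots per array with a non-uniformity mark were left out, and spots of 1 probe were averaged. A probe was tested where it was well above background on at least 3 of 4 arrays in 1 channel. For targets with several tested probes the brightest probe was used. No spot was saturated in either channel (0 spots).

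A target is a gene symbol where one could be assigned, and otherwise the transcript, clone or assembled sequence that the array design names. Several transcripts of 1 gene therefore count separately. Names came from a gene table of the Release 6 assembly, which was used for names, RNA classes and chromosome arms only, since the array design was annotated on an earlier assembly. Of 32171 probes, 326 could be paired with 1 gene (148 through a RefSeq accession, 20 through a synonym and 158 through a cDNA clone name held as a synonym), 2 matched several genes and 31843 stayed unnamed. FlyBase transcript identifiers were carried by 20801 of the probes, of which 12 were named, as synonyms in that table, and 20789 were not. The 326 probes covered 264 genes. No probe could be paired with the Hdac1 gene, so its transcript and its chromosomal neighbourhood were not analysed here. A clone name identifies the gene that the clone was assigned to, and the strand and position of the probe were not checked.

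The mean log2 ratio over the 4 arrays was tested against 0 with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all targets and a threshold of 0.05. Gene lists and clone groups of at least 3 tested members were compared with all other targets, and chromosome arms and RNA classes with the other named genes, by camera with a preset correlation of 0.01, and again with an estimated correlation, adjusted within each family of groups. The 34 gene lists, the tests and the rule for named genes were fixed before the data were examined. So were the alternatives, except the spike-in shift and some for chromosome arms, fry among them. The rule took the 6 largest rises and 6 largest falls among named genes past the threshold, with the same sign on 4 of 4 arrays and a symbol that is not a bare CG or CR number. Members of lists were named where the list was described. Groups of cDNA clones by source library were set after the identifiers had been read and before any ratio was computed. RNA classes and further single genes were chosen after their values were seen. Where a target was not well above background in 1 channel on all 4 arrays, a bound on its difference was computed per channel after loess and Aquantile. Such a bound is open to dye bias and to the centring of the arrays.

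The fit was tested on simulated log2 ratios for 21901 targets with the observed spread between arrays. It recovered 23.9% of 67 changes of 0.5 on the log2 scale, 80.6% of 67 changes of 1 and 93.9% of 66 changes of 2, and 2.94% of its calls were false. The adjusted threshold depends on the share of targets changed, which was far smaller here than the share called in the data, so these percentages do not carry over to the real comparison. The number of arrays, 4, limits the precision. Alternatives covered background correction, normalization, the filter on dim probes, the choice of probe, array weights, a fit of the channels as separate samples and the omission of each replicate.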

Results

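Transcript levels in larvae mutant for Hdac1, a histone deacetylase, were compared with those of wild type larvae on 4 arrays, each a direct hybridisation of mutant against wild type RNA. Between 84.8% and 86.5% of the spots on an array were well above background in the wild type channel, and between 84.0% and 86.8% in the mutant channel. Median spot intensities ran from 316 to 504 in the wild type channel and from 1490 to 1970.5 in the mutant channel. Across targets, the log2 ratios of pairs of arrays correlated with r between 0.925 and 0.958, and targets are not independent replicates. The median SD of a target's log2 ratio between arrays was 0.22.

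The comparison asked which transcripts differ in level between Hdac1 mutant and wild type larvae. Of 21901 targets tested, 16549 (75.6%) passed the threshold in limma with Benjamini-Hochberg adjustment, 8351 higher and 8198 lower in the mutant. At a change of at least 2-fold, 2421 targets were higher and 3560 lower. At least 4-fold, 348 were higher and 1066 lower, and at least 16-fold, 10 were higher and 93 lower. The lower targets made up 59.5% of the calls of at least 2-fold, against 49.8% with the scanner software's own log ratio and 42.7% with median centring in place of loess. The ratio had the same sign on all 4 arrays for 17747 targets (81.0%), where independent random signs give 12.5%. The dyes had the same orientation on all 4 arrays, so a dye bias of a target would also repeat its sign. In the mutant alone 242 targets were well above background on all 4 arrays, and in the wild type alone 278.

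All changes are relative to the centre of each array. Median centring moved the median of all targets by 0.10 on the log2 scale, and a shift set by the spike-in control probes, chosen after the data were seen and resting on spike amounts that are unknown here, moved it by 0.90. With that shift 15740 targets were higher and 2625 lower, so that 85.7% of the calls were higher, against 50.5% with loess. The largest changes belonged to targets without a gene name here. TC238685 rose by 5.85 ± 0.20 and FBtr0084847 by 5.24 ± 0.22 on the log2 scale (SD, n = 4), and FBtr0300627 changed by -7.84 ± 0.39 and FBtr0303731 by -7.03 ± 0.68.

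**Figure D1:**
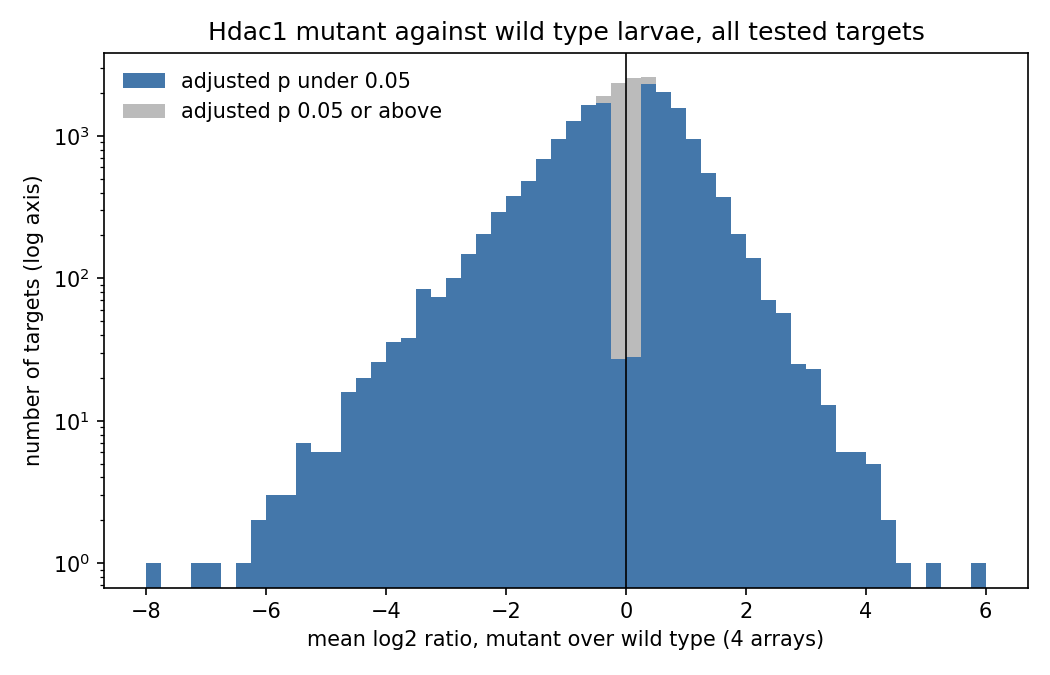
Number of targets (log axis) by mean log2 ratio of mutant over wild type over 4 arrays, in bins stacked by whether the limma adjusted p was under 0.05. Of 21901 targets, 16549 were past the threshold, and the tail of lower targets reached -7.84 against 5.85 for higher ones.

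Of 230 tested targets with a gene name, 176 passed the threshold, 71 of them higher and the others lower in the mutant. LysE, a lysozyme gene of the larval gut, rose by 2.51 ± 0.47 on the log2 scale, a 5.70-fold rise (SD, n = 4, limma adjusted p = 7.3e-07). UQCR-C2, a core subunit of mitochondrial respiratory complex III, rose by 2.17 ± 0.33, and alpha-Spec, which encodes the membrane skeleton protein alpha-spectrin, by 1.86 ± 0.35. The wuc gene rose by 1.35 ± 0.24, the spliceosomal RNA snRNA:U1:21D by 1.32 ± 0.53 and the small noncoding RNA sncRNA:158 by 1.19 ± 0.10. The U1 RNA is not polyadenylated, so its value on cDNA primed with oligo-dT depends on how that RNA was primed. Another U1 entry, snRNA:U1:82Eb, chosen after its values were seen, went the other way (-1.25 ± 0.79), so a rise of U1 RNA as such is not shown. With median centring the folds of 3 of these rises were over 1.5 times larger, with log2 ratios of 3.34 for LysE, 2.32 for snRNA:U1:21D and 1.80 for sncRNA:158.

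With loess the falls among named genes were larger, a ranking that rests on how each array is centred. Jhbp2, named for juvenile hormone binding, fell by 4.40 ± 0.56 on the log2 scale, a 21.2-fold fall (SD, n = 4, limma adjusted p = 6.7e-08). Tango14 fell by 3.59 ± 0.49. The chromatin regulator gene E(Pc), Enhancer of Polycomb, fell by 2.71 ± 0.95, and bic, which encodes a subunit of the nascent polypeptide-associated complex, fell by 2.34 ± 0.05. The cuticle protein gene Cpr60D fell by 2.24 ± 0.65. The noncoding RNA roX2, part of the male dosage compensation complex, fell by 2.19 ± 0.57. Its 2 probes gave -2.19 and -1.17. With the scanner software's log ratio the folds of 3 of these falls were over 1.5 times larger, with log2 ratios of -5.06 for Jhbp2, -4.42 for Tango14 and -3.05 for bic.

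**Figure D2:**
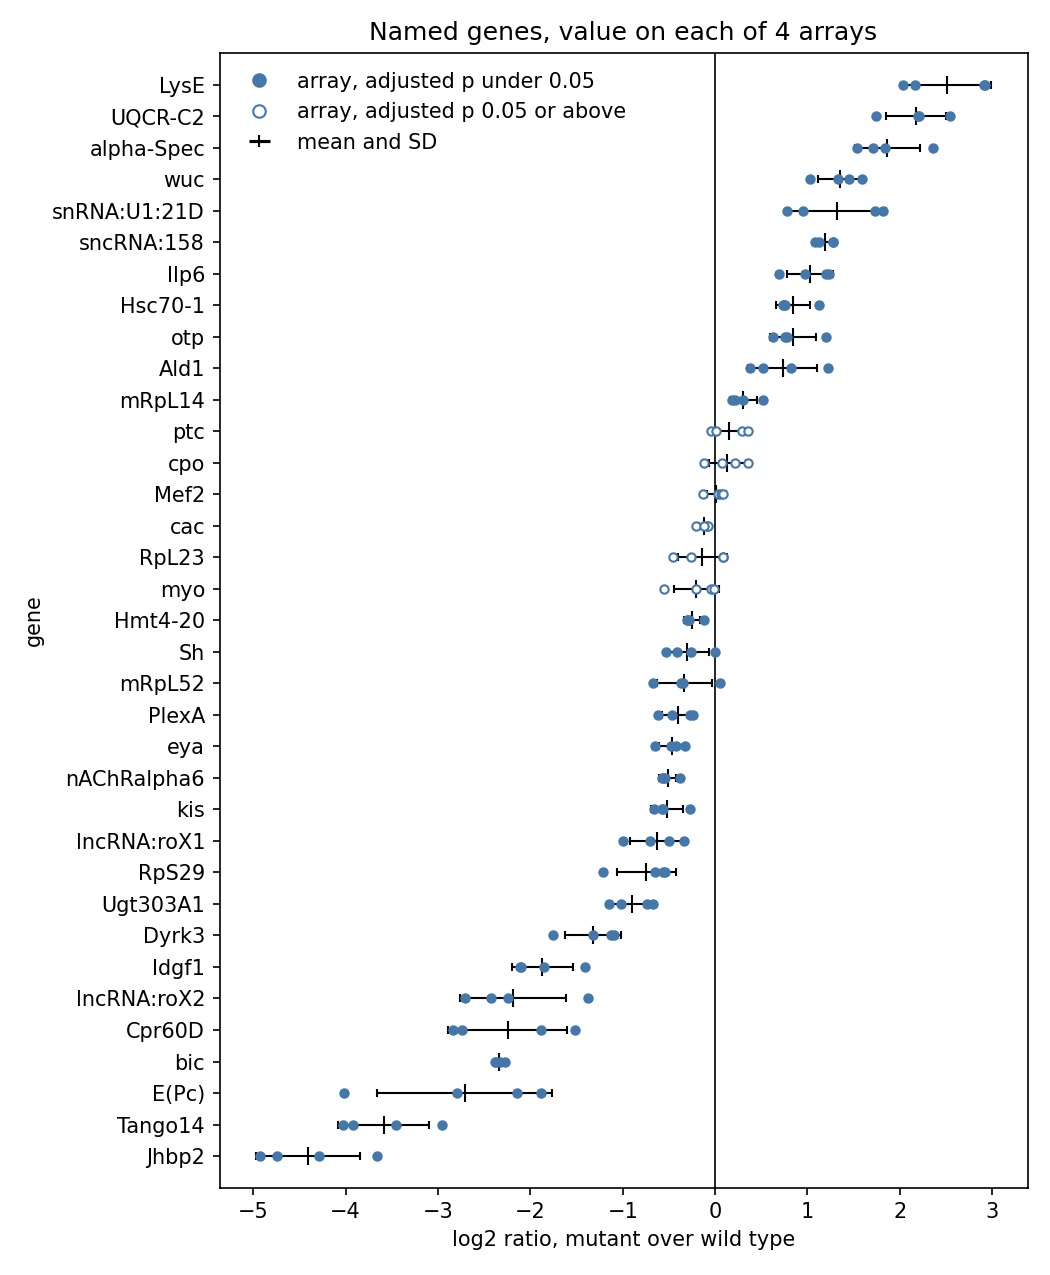
Log2 ratio of mutant over wild type for named genes on each of 4 arrays (points, filled where the limma adjusted p was under 0.05), with mean and SD. The genes shown are the largest rises and falls under the rule and the tested list members. Genes chosen after their values were seen, lncRNA:CR33948 at -5.48 among them, are left out. LysE lies at 2.51 and Jhbp2 at -4.40. Hmt4-20, PlexA, roX1, RpL23 and cac lie below 0 here, and above it with median centring (0.51, 0.018, 0.13, 0.73 and 0.11) and with the spike-in shift, which also turns eya, kis, mRpL52, myo, nAChRalpha6, RpS29 and Sh.

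The gene lists were set to ask whether tissues and pathways shifted, but few of their genes could be named, 1 of 83 for oxidative phosphorylation. Only 2 lists, chromosome 4 and neuronal genes, had at least 3 tested members and were tested as groups. Values from the other lists are those of single genes and describe no tissue or pathway. Members could be tested in 18 of 34 lists, 27 genes in all, of which 7 were higher, 14 lower and 6 past the threshold in neither direction. Of the metabolic and stress genes, Ilp6, an insulin-like peptide gene, rose by 1.03 ± 0.25, the glycolytic aldolase gene Ald1 by 0.73 ± 0.37 and Hsc70-1, a heat shock cognate gene, by 0.84 ± 0.19 (log2, SD, n = 4). The homeobox gene otp rose by 0.84 ± 0.25. Idgf1, which encodes a secreted chitinase-like growth factor, fell by 1.87 ± 0.33, and the UDP-glycosyltransferase gene Ugt303A1 fell by 0.90 ± 0.23, a fall lost with the spike-in shift (-0.0013). With the scanner software's log ratio Ilp6 was at 1.77 and Idgf1 at -2.69. Of the mitochondrial ribosomal protein genes, mRpL14 rose by 0.31 ± 0.15 and mRpL52 fell by 0.33 ± 0.30. The calls of both were lost with some single replicates left out, and the mRpL52 value was -0.02 with median centring and 0.56 with the spike-in shift. The probe of RpS29, a cytosolic ribosomal protein gene, gave -0.74 ± 0.32, but was well above background in the mutant on 1 of 4 arrays. That probe, named through a cDNA clone, had mean log2 signals of 7.8 in wild type and 7.1 in the mutant. RpL23 stood at 15.8 and 15.7, so whether the dim probe reads RpS29 messenger RNA is open. RpS29 stood at -1.66 with the scanner software's log ratio, -1.36 with median centring and 0.15 with the spike-in shift. RpL23 was at -0.14 ± 0.27, not past the threshold, and at 0.73 with median centring and 0.76 with the spike-in shift.

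Among genes of chromosome 4, a chromosome rich in heterochromatin, Dyrk3 fell by 1.32 ± 0.30 and PlexA, a semaphorin receptor gene, fell by 0.40 ± 0.18, while myo stood at -0.20 ± 0.25 (log2, SD, n = 4). PlexA was at -0.25, not past the threshold, with the scanner software's log ratio, and turned to 0.018 with median centring and to 0.50 with the spike-in shift. The myo value passed the threshold as lower with the scanner software's log ratio (-0.42) and with median centring (-0.54), and as higher with the spike-in shift (0.69). The 2 falls held adjusted over the list alone. The list's median lay -0.42 from that of other targets, which was not past the threshold in camera (adjusted p = 0.311, and adjusted p = 0.635 with an estimated correlation). Among chromatin genes, kis, a trithorax group remodelling factor, fell by 0.52 ± 0.17, but stood at -0.17, not past the threshold, with median centring and at 0.38 with the spike-in shift. Hmt4-20, a histone H4 methyltransferase gene, fell by 0.25 ± 0.08 (limma adjusted p = 0.043). Hmt4-20 was at 0.51 with median centring and 0.65 with the spike-in shift, and its call was lost without any 1 of the replicates.

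Of 4 neuronal genes tested, nAChRalpha6, a nicotinic receptor subunit gene, fell by 0.51 ± 0.09 and the potassium channel gene Sh fell by 0.30 ± 0.23, while cac was at -0.12 ± 0.06 and cpo at 0.13 ± 0.20 (log2, SD, n = 4). The call of Sh was lost without replicate 1, 2 or 4. With the spike-in shift nAChRalpha6 was at 0.38, Sh at 0.59 and cac at 0.77 (0.11 with median centring), and cpo passed the threshold at 1.03, as it did at 0.69 with median centring. Adjusted over the list alone 1 of the 2 falls held. The median of the list lay -0.23 from that of other targets (camera adjusted p = 0.455, and adjusted p = 0.635 with an estimated correlation). The eye and disc gene eya was well above background in the wild type on 3 of 4 arrays and in the mutant on none. It was 1.38-fold lower in the mutant with loess. Its bound equalled that estimate, so it sets no lower limit. The log2 ratio of eya was -1.94 with the scanner software's log ratio, -1.30 with median centring and 0.43 with the spike-in shift. Neither ptc (0.15 ± 0.20), whose 2 probes differed in sign, nor the muscle gene Mef2 (0.01 ± 0.10, and below 0 with median centring) was past the threshold, and both passed it with the spike-in shift, at 1.05 and 0.91.

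The RNAs roX1 and roX2 and the genes of each chromosome arm were also compared. The male-specific roX1 RNA fell by 0.63 ± 0.29 (log2, SD, n = 4, limma adjusted p = 0.0011), with 4 probes between -0.67 and -0.41, and turned to 0.13 with median centring and 0.26 with the spike-in shift. None of the 6 chromosome arm groups of named genes passed the threshold in camera. Their medians lay from -0.23 (5 genes of chromosome 4) to 0.22 (40 genes of arm 2L) from those of the other named genes, with adjusted p = 0.864 for each (adjusted p = 0.857 with an estimated correlation). With 1 replicate left out the shift of arm 2L ran from 0.083 to 0.25 and that of chromosome 4 from -0.29 to -0.16, and with median centring they were at 0.065 and -0.45.

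Targets named by cDNA clones were grouped by the library of the clone, which identifies a tissue where the transcript was once found and not one where it is restricted. Of 123 testis clones, 66 were lower and 35 higher, with a median -0.39 from that of other targets. The male-specific RNAs roX2 (-2.19 ± 0.57) and roX1 (-0.63 ± 0.29, turned upward with median centring and the spike-in shift) and the Y-linked gene CG40635 (-1.80 ± 0.47, chosen after its values were seen) were lower in the same larvae (log2, SD, n = 4). The testis group was not past the threshold in camera (adjusted p = 0.101, and adjusted p = 0.636 with an estimated correlation), and was past it at -0.62 with the scanner software's log ratio (adjusted p = 0.0223) and at -0.69 with median centring (adjusted p = 0.0021). Of 213 embryo clones, 103 were higher and 65 lower, with a median 0.21 above that of other targets (adjusted p = 0.350). Of 60 ovary clones, 25 were lower and 18 higher, at -0.09 (camera adjusted p = 0.742), and from -0.16 to -0.07 with 1 replicate left out. The groups of 208 head, 36 larva and pupa and 72 cell line clones lay at -0.01, -0.01 and -0.0020. With 1 replicate left out the larva and pupa shift ran from -0.0063 to 0.075. The head and the larva and pupa groups had medians below other targets, while camera gave them the direction up.

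**Figure D3:**
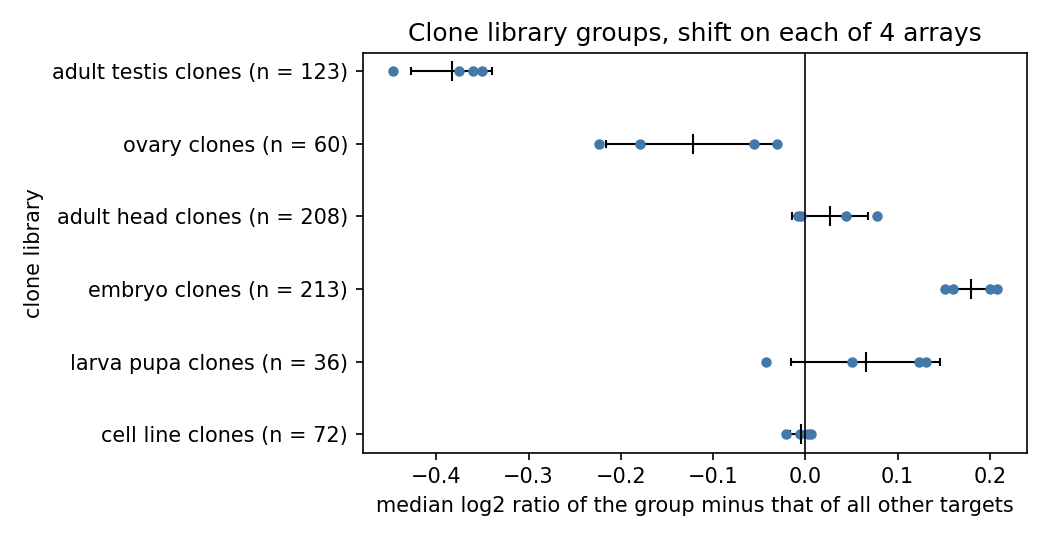
Median log2 ratio of the targets of each clone library minus that of all other targets, on each of 4 arrays (points), with mean and SD. Testis clones lie below 0 on 4 of 4 arrays and embryo clones above it on 4 of 4 arrays, and neither group was past the threshold in camera.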

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

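Every test of an explanation in this part was chosen after the result it bears on had been seen. The comparison of each array with the others was set beforehand.

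On 4 arrays, 1 array stood far from the other 3 for 5 of 72 values tested, where chance gives about 1 in 20, or 3.6. Replicate 2 stood apart for Hmt4-20 (-0.12, the others from -0.30 to -0.28) and for CG14762 (1.46, the others from 1.76 to 1.82), a gene chosen after its values were seen. Replicate 4 stood apart for Hsc70-1 (1.12, the others from 0.74 to 0.76), nAChRalpha6 (-0.38, the others from -0.57 to -0.54) and RpS29 (-1.21, the others from -0.65 to -0.54). All values are log2 ratios of mutant over wild type.

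Most targets, 75.6%, differed between mutant and wild type. Over the 8 ways of turning the signs of the 4 arrays, the real one gave 16549 targets and the highest other 0, and 8 are too few for a share under 0.05. Over 35 splits of the 8 channels, 1 split, the real one with 14948 targets, gave as many, and the highest other gave 0, but these splits ignore that 2 channels share an array, so they add nothing on chance to the 8 paired ones. A dye bias tied to single probes could add to the count. Of targets that differed at least 2-fold at a first probe, 85.0% had the same sign at a second probe. This is above the 50% of such a bias alone, but the probes may overlap in sequence. Across 4686 targets with at least 2 tested probes, the ratios of the first 2 correlated with r = 0.63, lower than the 0.925 to 0.958 between arrays. Each call rests on 1 probe, the brightest. Without a dye swap, dye and genotype cannot be told apart, and the difference between genotypes stays open beside it.

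The spike-in probes, a control signal that the comparisons do not use, lay -0.90 from the centre of the transcripts on the log2 scale in the mutant channel (mean of 4 arrays, from the header's fit). The 10 probes ran from -4.17 to 1.78, 5 of them below 0, and their median per array from -0.92 to -0.55. The header's fit uses expected ratios that differ between probes, so the range of the 10 probes is not scatter around 1 value. A separate error in the spike amount on each array is argued against, since the mean shift of 0.895 had an SD of 0.202 between arrays and the same sign on 4 of 4. An unequal spike amount or a dye effect shared by the arrays may be the source: observed and expected spike ratios correlated with r of 0.709 at the lowest and 0.831 at the highest, too low to show that 1 common shift describes the probes. The labels mention no spike-in and its amounts are unknown here, so the shift is no measured scale. A larger amount of messenger RNA per total RNA in the mutant also stays open, untested.

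The male-specific RNAs roX1 and roX2 and the Y-linked gene CG40635 (-1.80 ± 0.47, SD, n = 4, chosen after its values were seen) were lower in the mutant, beside a testis clone group at -0.39 that was not past the threshold. Normalization within arrays is argued against for roX2 and CG40635. Both stayed lower past the threshold with loess, the scanner software's log ratio and median centring, the smallest fall being -1.80. The rest of the 6 settings tried repeated these ratios or changed only the background correction. For roX1 normalization is a candidate cause, since roX1 reached 0.13 with median centring. A lower share of male larvae in the mutant samples may contribute. The roX1 probes ran from -0.67 to -0.41 and the roX2 probes from -2.19 to -1.17, without overlap. Their nearest probes differed by 0.50, less than the 1.02 between the 2 probes of roX2. Taking the nearest pair gives the smallest gap and so favours equal falls, and the comparison cannot decide whether the 2 RNAs fell equally. CG40635, at -1.80, also lay below all roX1 probes. It has 1 probe and was chosen after its value was seen, so it cannot decide this either. The sex of the larvae is not given in the labels used here. A direct effect of the genotype on these RNAs also stays open, untested.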

How the results depend on the processing

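The spike-in shift, the clone groups, the RNA classes, the further single genes and some alternatives for chromosome arms, fry among them, were chosen after the data or identifiers were seen. The other alternatives were set before the data were examined. Of 51 named genes, 38 kept their call (higher, lower or neither) without a reversal under each of the 17 settings, other than the spike-in shift, that gave them a value. The filter on both channels left out eya, RpS29 and lncRNA:CR33948, which have 16. Among the 38, cac, Mef2 and ptc changed sign under some setting while past the threshold neither way, and 35 kept both call and sign. The 13 others, whose call was lost, gained or reversed, were Cyp1, Hmt4-20, PlexA, RNaseMRP:RNA, RpL23, Sh, cpo, kis, Hsromega, roX1, mRpL14, mRpL52 and myo. The cause of a change was not tested unless stated.

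The count past the threshold ran from 15216 to 15932 with 1 replicate left out (7562 to 8048 higher, 7654 to 7884 lower). At least 2-fold, it ran from 2192 to 2610 higher and from 3313 to 3778 lower. A 2-fold minimum left 5981 targets, 2421 higher and 3560 lower, by its construction. Targets at least 2-fold higher numbered 4158 with the scanner software's log ratio, 4158 with the submitters' table, which holds the same values, and 4275 with median centring. The spike-in shift gave 15740 higher and 2625 lower, and at least 2-fold 10111 higher and 1198 lower, since it adds a mean of 0.895 to every ratio. As a constant per array it cannot move a group median relative to other targets, and the group tests were not rerun with it. Without the pairing of channels by array, the fit with no replicate block gave 14948 targets, 7451 higher and 7497 lower.

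With median centring, Hmt4-20 reversed to 0.51, roX1 to 0.13, PlexA to 0.018, RpL23 to 0.73 and RNaseMRP:RNA to 0.065 (log2). With the spike-in shift the reversed values were cac 0.77, eya 0.43, Hmt4-20 0.65, kis 0.38, roX1 0.26, mRpL52 0.56, myo 0.69, nAChRalpha6 0.38, PlexA 0.50, RpL23 0.76, RpS29 0.15 and Sh 0.59. Folds that moved by over 1.5 times are given with their genes. The lncRNA:Hsromega value of 0.35 was at 1.21 with median centring, but its 4 probes ran from -0.23 to 0.35, and its call was lost with the mean of its probes (0.035) and without replicate 2 (0.30).

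The testis clone shift passed the threshold at -0.62 with the scanner software's log ratio and the submitters' table and at -0.69 with median centring. It ran from -0.41 to -0.35 with 1 replicate left out. With an estimated correlation the RNA class shifts, 0.60 for protein-coding and -0.60 for noncoding RNAs, were no longer past the threshold. The fry test asks whether a group's own mean differs from 0 and not whether it differs from other genes, so its results answer another question. It passed the threshold for chromosome 4 list genes (mean -0.64), neuronal genes (-0.20), testis (-0.42), ovary (-0.20), embryo (0.12) and larva and pupa clones (0.13). It also passed, always downward, for arms 3R (-0.49), 4 (-0.48) and X (-0.46) and noncoding RNAs (-1.03), and for arms 2L (-0.20), 2R (-0.22) and 3L (-0.27) and protein-coding genes (-0.19), to which camera gave the direction up.

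Not run were a correction for probe base composition, since probe sequences were not used here, a slide block, since all arrays share 1 slide, and the results for the Hdac1 transcript and its neighbours, since no probe was paired with that gene. Leaving out saturated probes removed none and tests nothing. Signal over background limits dim targets: without the filter 25679 targets were tested and 17260 passed.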

Other observations

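The genes and RNA classes in this part were chosen, and their tests run, after their values were seen.

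Several long noncoding RNAs had large falls in the mutant. The RNA lncRNA:CR33938 fell by 4.12 ± 0.38 on the log2 scale and lncRNA:CR33948 fell by 5.48 ± 1.04 (SD, n = 4), the latter well above background in the mutant on 2 of 4 arrays and at -7.08 with the scanner software's log ratio. Of 32 named long noncoding RNAs, 23 were lower and 5 higher. With 7 antisense RNAs and 2 other noncoding RNAs, 1 of them the small sncRNA:158, the group tested held 41 RNAs, 28 lower and 8 higher, against 67 lower and 60 higher of 171 protein-coding genes. The median of the noncoding group lay -0.60 from that of other named genes (camera adjusted p = 0.0056, and adjusted p = 0.352 with an estimated correlation). The group was picked from these data and holds only RNAs that could be named.

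Of 5 spliceosomal RNAs tested, 4 were lower and 1 higher. The values of snRNA:U2:34ABb, snRNA:U1:82Eb and snRNA:U12 were -1.28 ± 0.47, -1.25 ± 0.79 and -1.20 ± 0.59 (log2, SD, n = 4), while snRNA:U1:21D rose. The U12 call was lost with the spike-in shift (-0.31), and snRNA:U2:34ABb was at -0.49 with median centring. The probes of snRNA:U1:82Eb and snRNA:U12 were dim, with mean log2 signals of 9.5 and 9.3 in wild type and 8.2 and 8.1 in the mutant. The signal recognition particle RNA 7SLRNA:CR32864 fell by 1.41 ± 0.52. These RNAs are not polyadenylated. The 3 probes of Cyp1 ran from -1.39 to 1.19, and the mean of its probes, 0.16, was not past the threshold.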
